A study of Mus musculus with 2 samples.

How the data were processed

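Mouse lung macrophages were measured in 1 group of 2 libraries. Per the labels, Balb/C mice received 4T1-Luc cells in mammary gland number 4, lungs were taken after 5 weeks, and macrophages were sorted by flow cytometry after collagenase digestion. Libraries were made with the 10x Chromium 3' kit, version 2, per the labels' protocols. Per the submitters' processing notes, the authors used Cell Ranger 3.0.2, Seurat 3.1.1 and the GRCm38 genome; the notes give neither the order of the steps nor the filters on cells and genes.

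The authors deposited tables of raw UMI counts, per the file headers, for each library alone and for both merged. The merged table held 12546 cells and 14424 genes, and the column sums of 0 cells differed from the totals the authors deposited. The authors' processed tables hold the natural log of 1 + 10000 times each gene's share of the cell's UMIs, checked to within 6.22e-15, and were not used further. Per the file headers, the authors also deposited cluster numbers made at resolution 0.3 on integrated data for the merged cells, and at 0.6 and 0.5 for libraries 1 and 2 alone. The single-library tables held 10954 and 1561 cells. The merged table held 25 and 6 more, with medians of 21848 and 19860.5 UMIs, and all its cells were used. Of its genes, 12111 are listed for both libraries, 2222 for library 1 only and 91 for library 2 only, with 0 UMIs in the other library.

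Cells held 500 to 32260 UMIs in library 1 and 508 to 67341 in library 2. Shares carry exact 95% Clopper-Pearson intervals, and a count of 0 is given the limit of 3 counts. Clusters are the authors' merged ones. The marker lists, the functional lists, the tests, the rule for named genes and most alternatives were written before the data were examined. Cluster names were given by comparing these markers with each cluster's 10 genes of highest fold among genes with at least 50 CPM (pseudocount 10 CPM). The plan compared named clusters; clusters 0, 3 and 4 took no name and were compared by number.

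UMI counts were summed per library and cluster for clusters with at least 10 cells in each library, which left out cluster 10 and gave 20 sums. They were fitted with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood test, two-sided), with the library as a block and 9 residual degrees of freedom, and Benjamini-Hochberg adjustment at 0.05. These degrees of freedom come from clusters of the same 2 libraries, so the p-values do not speak for further animals. Clusters 6, 8 and 9, named for other cell types, and cluster 10 were left out of the macrophage-like reference. Each macrophage-like cluster was set against the equal-weight mean of the others, and the lipid-associated-like cluster also against the alveolar-like one. Levels with an SD are CPM of TMM-scaled totals; levels given per library without an SD are CPM of unscaled totals. Errors beside a log2 fold are standard errors, taken as the fold divided by the square root of edgeR's F. For named genes and printed list medians, library-alone values are given where they left the fitted value by more than 1.5-fold or changed sign.

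The 17 functional lists hold 267 genes, of which 254 were tested, and no naming marker. They were tested with camera (limma 3.58.1, inter-gene correlation 0.01, at least 3 members), adjusted over the lists for the comparisons of the lipid-associated-like cluster, and over lists and clusters for the rest. Named genes are, per list, the 2 called members of largest absolute fold with the same direction in both libraries, or the most abundant member where none was called, plus the lipid-associated markers and each cluster's 10 leading genes. For the other clusters this rule was applied to the lists past camera's threshold, a choice made after values were seen, as was the choice of levels printed in CPM. Some genes that the rule names are not reported here.

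The edgeR step was tested on simulated data for the lipid-associated-like comparison, with 200 changed genes of 8535 and a further shifted gene list. It recovered 63% of 2-fold and 94% of 4-fold changes, all with the right sign. Of 184 calls, 7 (3.80%) were false. Clustering on the same counts was not simulated.

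Cells were thinned to 1000 UMIs for cycling shares, leaving out shallower cells, where at least 3 UMIs over the cycling markers were required. Markers of other types needed at least 2 UMIs. Alternatives set out in advance were edgeR's RLE size factors, no low-count filter, the Wald test of DESeq2 1.42.0, no library block, thinned cells, a fit of 2 clusters alone, the other clusters summed as a single arm, Scrublet doublets left out, own Leiden clusters, count splitting (probability 0.5), at least 30 cells per library, each library left out, an estimated inter-gene correlation, the list median against 10000 random lists matched on expression in 20 bins, and other minimums. Own clusters used leidenalg 0.10.2 on a shared-neighbour graph (2000 genes, 30 components, 20 neighbours, resolution 0.3) in Python 3.11.15. Scrublet was run through scanpy 1.11.5, and the models ran in R 4.3.3. Chosen after seeing the data were genes listed for both libraries, leaving out cluster 3, leaving out cycling clusters 2 and 7, and leaving out the top 5% of Scrublet scores. Scrublet called 1 of 10979 cells (0.00911%) in library 1, where its threshold did not separate doublets, and 8 of 1567 (0.511%) in library 2.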

Results

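Lung macrophages were sorted from Balb/C mice 5 weeks after cells of 4T1-Luc, a luciferase-marked mouse mammary carcinoma line that spreads to the lung, had been placed in a mammary gland. The single group had 2 single-cell libraries, replicates 1 and 2. Library 1 held 10979 cells and 51136887 unique molecular identifier (UMI) counts, with medians of 3724 UMIs and 1417 genes per cell. Library 2 held 1567 cells and 12314406 UMIs, with medians of 6225 UMIs and 1675 genes. The median mitochondrial share was 3.64% in library 1 and 5.42% in library 2. No tumour-free lungs were measured, so each comparison is between clusters of cells of the same tumour-bearing lungs. The labels do not say whether the libraries came from separate animals, so the p-values do not speak for further animals.

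The first question was which kinds of macrophage the sorted cells held. Cluster 5 of the authors' 11 merged clusters was led by Gpnmb, a lysosomal membrane glycoprotein, Syngr1, Fabp5, a fatty acid carrier, and the protease Ctsl. It held 9 of 12 lipid-associated markers at more than 2-fold over the other clusters and is called lipid-associated-like. Cluster 1 was led by Ear1, Plet1, Ear2, Lpl and Car4, held 12 of 13 alveolar macrophage markers over 2-fold, and is called alveolar-like. Ear1 and Ear2 are near copies, so the split of reads between them is uncertain. Clusters 2 and 7 each held 14 of 14 cycling markers over 2-fold. Cluster 2, led by Pclaf, Ube2c and Top2a, is called cycling-like. Cluster 7, with 9 of 13 alveolar markers but 0 leading ones, is cycling alveolar-like. Cluster 6 was neutrophil-like, with 11 of 11 markers such as S100a9, Retnlg and Ngp. Cluster 8 was T cell-like, with 7 of 7 markers such as Trbc2 and Cd3g, 3 of 6 NK cell and 3 of 6 B cell markers. Cluster 9 was dendritic-like, with 5 of 9 conventional dendritic and 8 of 8 antigen-presenting markers, and was led by Ccl17 and Cd209a. These leading genes define their clusters and are not findings.

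Clusters 0, 3, 4 and 10 took no name. Cluster 0 was led by the chemokine Ccl12 with Ms4a4c, Cxcl9 and Plac8. It held 8 of 12 interstitial, 6 of 8 antigen-presenting, 4 of 9 classical monocyte and 3 of 12 interferon markers over 2-fold, but 0 leading interstitial ones. Cluster 3 was led by mitochondrial transcripts such as mt-Nd1 and mt-Cytb, with Maf, Cxcl13 and Stab1, and held 4 of 12 interstitial markers. Cluster 4 was led by Arg1, which consumes arginine, Il6, Alox15 and Prtn3. Cluster 10 was led by keratins Krt8 and Krt18 with Wfdc2. It held 2 of 7 epithelial or tumour cell, 4 of 6 alveolar type 2, 6 of 14 cycling, 3 of 12 interferon and 1 endothelial marker. No cluster held more than 1 of 9 nonclassical monocyte, 1 of 6 plasmacytoid dendritic, 1 mast cell or 1 platelet marker over 2-fold. No eosinophil, fibroblast or erythroid marker passed. Only 1 of 5 eosinophil, 2 of 6 mast cell, 2 of 4 platelet and 4 of 6 B cell or alveolar type 2 markers had data. No cluster was named interstitial-like, so that planned comparison was not made. The naming was uneven here: cluster 7 is called alveolar-like, also with 0 leading alveolar markers.

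Lipid-associated-like cells made up 5.56% of library 1 (95% Clopper-Pearson interval 5.13 to 6.001, 610 cells) and 4.66% of library 2 (3.67 to 5.82, 73 cells). Of the cells in macrophage-like clusters, which held 93.3% and 95.6% of the libraries, they made up 5.95% (5.503 to 6.43) and 4.87% (3.84 to 6.09). Alveolar-like cells were 28.2% (27.3 to 29.01) of library 1 and 13.6% (11.9 to 15.4) of library 2. Cluster 4 was 5.65% (5.22 to 6.095) and 16.8% (15.03 to 18.8), and cluster 0 was 27.9% (27.04 to 28.7) and 34.8% (32.4 to 37.2). Cluster 3 was 8.32% (7.81 to 8.85) and 13.5% (11.9 to 15.3), and cycling-like cluster 2 was 15.8% (15.1 to 16.5) and 11.6% (10.01 to 13.2). Cluster 7 was 1.99% (1.73 to 2.26) and 0.638% (0.306 to 1.17). Neutrophil-like cells were 4.07% (3.71 to 4.46) and 1.28% (0.781 to 1.96), T cell-like cells 1.26% (1.06 to 1.48) and 1.91% (1.295 to 2.72), and dendritic-like cells 0.984% (0.808 to 1.19) and 0.830% (0.442 to 1.41). Intervals and zero-count limits here cover counting error only. Of these 10 clusters, the intervals of the libraries overlapped for lipid-associated-like, T cell-like and dendritic-like cells and were apart for the other 7. No test between them was made because both belong to the same group.

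**Figure D1:**
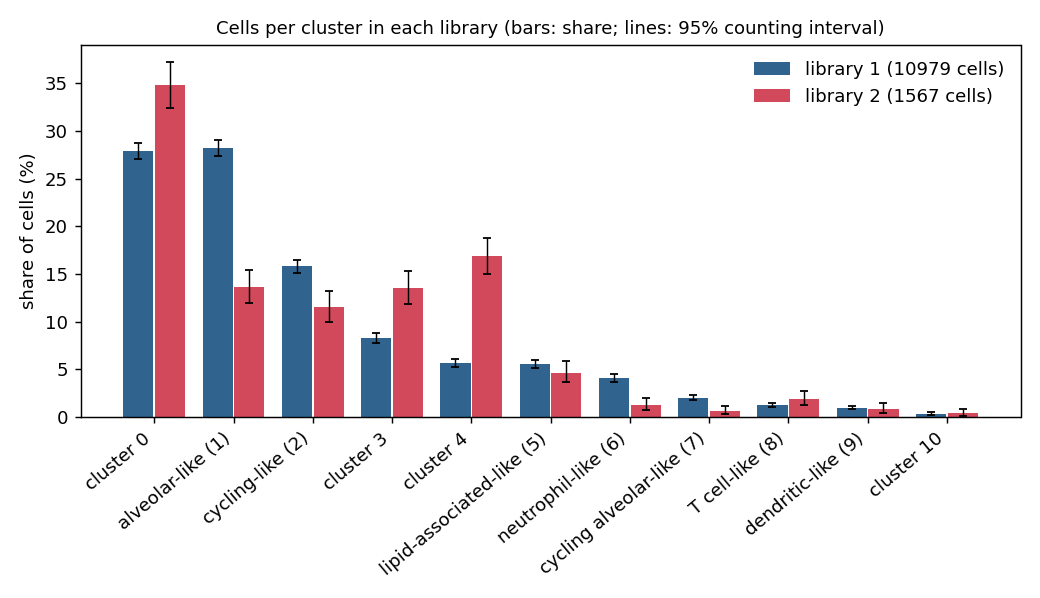
Share of cells (percent) in each of the authors' merged clusters, in library 1 (10979 cells) and library 2 (1567 cells), with 95% Clopper-Pearson intervals as lines. The lipid-associated-like cluster held 5.56% and 4.66% of the cells, and cluster 4 held 5.65% and 16.8%.

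The second question was which genes set the lipid-associated-like cluster apart from the other macrophage-like clusters. Of 12 naming markers, 11 were higher and 1 was not past the threshold. Gpnmb stood at 1446 ± 1.499 CPM (SD, n = 2) against 58.9 ± 1.57 in the others, in CPM of TMM-scaled totals as for the other levels with an SD. Gpnmb (log2 4.86 ± 0.18, adjusted p = 1.54e-25) was the naming marker with the largest fold. Fabp5 stood at 2718 ± 163 CPM (SD, n = 2) against 332 ± 159 and Trem2 at 855 ± 6.78 CPM (SD, n = 2) against 300.1 ± 127. Fabp5 (log2 3.24 ± 0.21, adjusted p = 4.81e-17), Trem2, a lipid-sensing receptor (log2 1.66 ± 0.18, adjusted p = 8.13e-10) and Plin2, the coat of lipid droplets (log2 1.63 ± 0.20, adjusted p = 3.12e-08) were higher. So were Syngr1 (log2 4.01 ± 0.17, adjusted p = 1.73e-23), Cd63 (log2 2.35 ± 0.21, adjusted p = 1.83e-12) and Ctsd (log2 2.03 ± 0.20, adjusted p = 3.69e-11). Lgals3 (log2 1.69 ± 0.19, adjusted p = 3.48e-09), Capg (log2 1.02 ± 0.19, adjusted p = 9.27e-05) and Spp1 (log2 0.89 ± 0.22, adjusted p = 0.00256) were higher too. Cd9 (log2 0.66 ± 0.21, adjusted p = 0.02302) was higher by the fit, which averages logarithms over the clusters, although it stood at 1087 ± 90 CPM (SD, n = 2) against 1144 ± 136, with 3216 CPM in the alveolar-like cluster. Lpl, the secreted lipase that frees fatty acids (log2 -0.56 ± 0.32, adjusted p = 0.276) was not past the threshold, although it was past it and lower under count splitting and with the other clusters summed as a single arm (adjusted p from 3.31e-05 to 0.893 over the alternatives). These markers chose the cluster, so their folds describe it. Of 8932 genes tested with edgeR, 796 were higher and 535 lower, 389 and 342 of them by at least 2-fold, and 94.7% of them had the same direction in both libraries. The clusters were made from the same expression values, so p-values here and below are too small. In library 2 alone, the log2 was 3.24 for Syngr1, 1.61 for Cd63, 2.61 for Fabp5 and 0.22 for Lpl. Cd9 lost the call with thinned cells, with a single summed arm and without cluster 3. On GRCm38 the genes lie at Gpnmb (chromosome 6, 49036546 to 49070929), Fabp5 (chromosome 3, 10012548 to 10016607), Trem2 (chromosome 17, 48346401 to 48354147) and Ctsl (chromosome 13, 64359337 to 64370890).

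Function was read on 17 gene lists that held no naming marker, tested with camera. In the lipid-associated-like cluster, lysosomal, lipid, matrix, growth factor, iron and MHC class I lists were higher and cholesterol synthesis was lower. These 7 calls used a preset correlation between genes of 0.01. All ended with an estimated correlation, with which camera called 0 lists in this and in every other comparison, with adjusted p from 0.0639 here upward and, at an unadjusted p under 0.05, 4 higher and 0 lower lists here. Ctsl stood at 3614 ± 1944 CPM (SD, n = 2) against 549 ± 371, Cd36 at 117 ± 35.3 CPM (SD, n = 2) against 24.2 ± 4.77 and Mmp12 at 1100.2 ± 447 CPM (SD, n = 2) against 159 ± 3.03. Lysosome genes were higher (median log2 0.89, adjusted p = 3.86e-23, 19 higher and 0 lower of 23, 21 and 0 adjusted over the list alone). The lysosomal proteases Ctsl (log2 2.86 ± 0.20, adjusted p = 1.32e-15) and Ctsb (log2 2.31 ± 0.17, adjusted p = 1.06e-14) were higher. Genes of lipid uptake, storage and efflux were higher (median log2 0.67, adjusted p = 2.42e-04, 9 higher and 0 lower of 19, 9 and 1 adjusted over the list alone). Fabp4, a fatty acid carrier (log2 2.49 ± 0.25, adjusted p = 5.21e-11) and Cd36, a scavenger receptor for fatty acids (log2 2.35 ± 0.26, adjusted p = 8.93e-10) were higher. Cholesterol synthesis genes were lower (median log2 -1.03, adjusted p = 2.49e-06, 0 higher and 12 lower of 16, 0 and 13 adjusted over the list alone). Sqle, an enzyme of sterol synthesis (log2 -1.77 ± 0.36, adjusted p = 3.37e-04) was lower. Matrix genes and proteases were higher (median log2 0.48, adjusted p = 2.27e-06, 7 higher and 1 lower of 15, 7 and 1 adjusted over the list alone). Mmp12, the macrophage elastase (log2 2.91 ± 0.19, adjusted p = 1.45e-16) and Timp2, a protease inhibitor (log2 2.49 ± 0.18, adjusted p = 7.44e-15) were higher. Growth and angiogenic factors were higher (median log2 0.45, adjusted p = 8.53e-04, 4 higher and 0 lower of 15, 5 and 0 adjusted over the list alone). Igf1, a growth factor (log2 2.65 ± 0.24, adjusted p = 4.79e-12) and Pdgfa, a mesenchymal growth factor (log2 2.57 ± 0.20, adjusted p = 3.50e-14) were higher. Iron and oxidative stress genes were higher (median log2 0.88, adjusted p = 2.32e-07, 9 higher and 0 lower of 14, 9 and 0 adjusted over the list alone). Slc11a1, a metal transporter of phagosomes (log2 1.65 ± 0.20, adjusted p = 1.13e-08) and Fth1, the ferritin heavy chain (log2 1.42 ± 0.19, adjusted p = 1.28e-07) were higher. MHC class I presentation genes were higher (median log2 0.36, adjusted p = 0.00865, 4 higher and 0 lower of 9, 4 and 0 adjusted over the list alone). H2-D1 (log2 1.54 ± 0.18, adjusted p = 7.81e-09) and H2-K1 (log2 0.87 ± 0.21, adjusted p = 0.00197) were higher. Sqle rested on 16 UMIs in library 1 and 3 in library 2. Reads of H2-D1 and H2-K1, which are near copies, and of Fth1, which has pseudogenes, could be split or shared. From library 2 alone came a log2 of 3.25 for Cd36, -0.34 for Sqle, -0.15 for the cholesterol synthesis list and 1.22 for the growth factor list. The growth factor list lost the call with thinned cells. The MHC class I list lost the call with a single summed arm and against random lists.

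The other 10 lists did not pass camera in the lipid-associated-like cluster, although single members passed. Chemokines and complement were past the threshold and lower against random lists, with medians at percentiles 0 and 0.26. Over all alternatives, chemokines passed as lower in 3, complement in 6, and glycolysis, hypoxia, oxidative phosphorylation and dissociation genes in 1 each. Mfge8 stood at 252 ± 233 CPM (SD, n = 2) against 14.7 ± 5.91. Fatty acid oxidation genes did not pass (median log2 0.09, adjusted p = 0.849, 1 higher and 0 lower of 15, 0 and 0 adjusted over the list alone). Acadl (log2 0.59 ± 0.20, adjusted p = 0.03495) was higher. Glycolysis genes did not pass (median log2 -0.17, adjusted p = 0.7495, 1 higher and 0 lower of 14, 1 and 0 adjusted over the list alone). Hk3, a hexokinase (log2 1.28 ± 0.20, adjusted p = 3.56e-06) was higher. Oxidative phosphorylation genes did not pass (median log2 -0.13, adjusted p = 0.508, 0 higher and 0 lower of 19, 0 and 0 adjusted over the list alone). Cox4i1, a subunit of cytochrome oxidase (log2 0.07 ± 0.21, adjusted p = 0.876), the member with the highest mean count, was not past the threshold. Inflammatory cytokines did not pass (median log2 -0.18, adjusted p = 0.921, 2 higher and 2 lower of 16, 2 and 2 adjusted over the list alone). Il1rn, the interleukin 1 antagonist (log2 0.81 ± 0.20, adjusted p = 0.00252) was higher. Cxcl3, a neutrophil attractant (log2 -2.71 ± 0.80, adjusted p = 0.01502) was lower. Chemokines did not pass (median log2 -0.60, adjusted p = 0.3902, 1 higher and 3 lower of 14, 2 and 5 adjusted over the list alone). Cxcl16, a lipid-binding chemokine (log2 1.28 ± 0.19, adjusted p = 1.67e-06) was higher. Cxcl13, a B cell attractant (log2 -1.92 ± 0.55, adjusted p = 0.0114) was lower. Immune regulation genes did not pass (median log2 0.04, adjusted p = 0.849, 1 higher and 1 lower of 14, 2 and 1 adjusted over the list alone). Pirb, an inhibitory receptor (log2 0.54 ± 0.18, adjusted p = 0.02901) was higher. Slamf9, a SLAM family receptor (log2 -0.73 ± 0.22, adjusted p = 0.0152) was lower. Phagocytosis genes did not pass (median log2 0.03, adjusted p = 0.226, 2 higher and 1 lower of 17, 3 and 1 adjusted over the list alone). Mfge8, a bridge between apoptotic cells and phagocytes (log2 3.97 ± 0.21, adjusted p = 7.48e-20) and Cd93, a surface glycoprotein (log2 1.43 ± 0.17, adjusted p = 7.44e-09) were higher. Complement genes did not pass (median log2 -0.57, adjusted p = 0.275, 1 higher and 2 lower of 7, 1 and 3 adjusted over the list alone). C3ar1, an anaphylatoxin receptor (log2 1.41 ± 0.22, adjusted p = 2.55e-06) was higher. C5ar1, an anaphylatoxin receptor (log2 -1.19 ± 0.24, adjusted p = 2.37e-04) was lower. Hypoxia response genes did not pass (median log2 -0.33, adjusted p = 0.508, 0 higher and 0 lower of 10, 0 and 0 adjusted over the list alone). Mif, a cytokine (log2 -0.37 ± 0.27, adjusted p = 0.415), the member with the highest mean count, was not past the threshold. Dissociation and early response genes did not pass (median log2 0.09, adjusted p = 0.849, 1 higher and 1 lower of 17, 1 and 1 adjusted over the list alone). Atf3, a stress-induced transcription factor (log2 0.94 ± 0.18, adjusted p = 1.55e-04) was higher. Hspa1b, a heat shock protein (log2 -1.20 ± 0.24, adjusted p = 2.88e-04) was lower. Cxcl13 rested on 11 and 0 UMIs, and Cxcl3 on 2 and 4. Immune regulation had a mean of -0.27, and the dissociation list a mean of -0.03, against positive medians. Library 1 alone gave a log2 of 3.23 for Mfge8. In library 2 alone, the log2 was 0.52 for Hk3, -0.21 for Cxcl3, -4.77 for Cxcl13, 5.21 for Mfge8, 0.80 for C3ar1, -1.79 for C5ar1, -0.22 for the fatty acid oxidation list, 0.65 for the inflammatory list, -0.08 for the phagocytosis list and -0.07 for the dissociation list. Acadl and Pirb lost their calls without a low-count filter. Acadl, Il1rn, Cxcl13, Slamf9, Pirb, Hspa1b and Atf3 lost their calls with thinned cells. Acadl, Cxcl16 and Pirb lost their calls with a single summed arm. Acadl and Cxcl3 lost their calls by DESeq2. Acadl and Cxcl13 lost their calls without cluster 3. Pirb lost the call without cycling clusters.

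**Figure D2:**
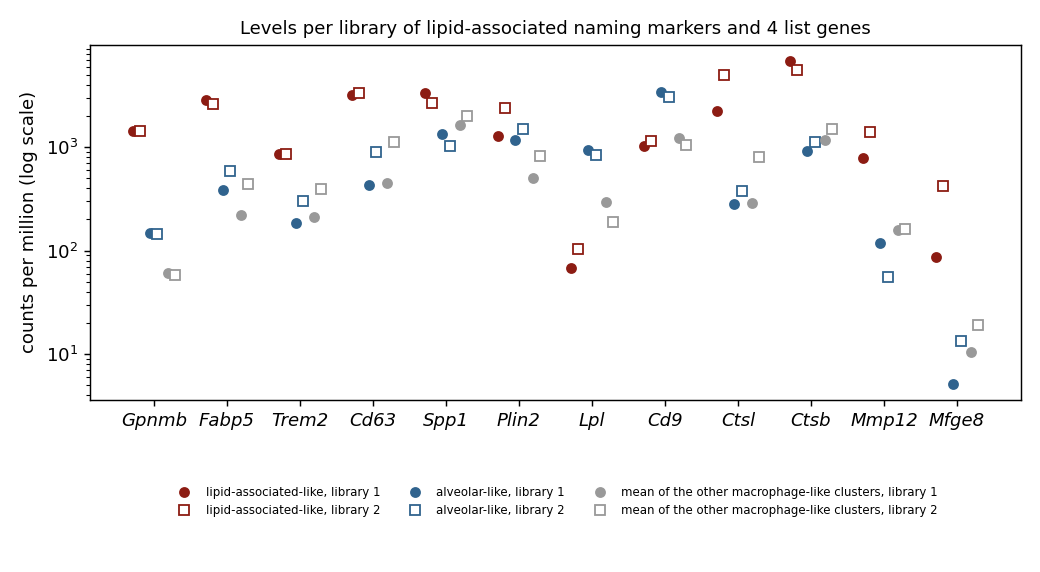
CPM (log scale) in each library of 8 lipid-associated naming markers and 4 list genes, for the lipid-associated-like cluster, the alveolar-like cluster and the mean of the other macrophage-like clusters. By the mean over libraries, Lpl and Cd9 stood higher in the alveolar-like cluster, at 898 and 3216, and the other 10 genes in the lipid-associated-like cluster.

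The alveolar macrophage also handles lipid, through surfactant, so the lipid-associated-like cluster was set against the alveolar-like cluster. The lipid genes parted. Lpl stood at 85.1 ± 24.7 CPM (SD, n = 2) against 898 ± 71.3 in the alveolar-like cluster, and Gpnmb at 1446 ± 1.499 CPM (SD, n = 2) against 147 ± 3.398. Lpl (log2 -3.51 ± 0.40, adjusted p = 2.52e-09) and Cd9 (log2 -1.57 ± 0.29, adjusted p = 5.33e-05) were lower. Gpnmb (log2 3.28 ± 0.31, adjusted p = 2.13e-11), Fabp5 (log2 2.60 ± 0.34, adjusted p = 9.90e-08) and Trem2 (log2 1.91 ± 0.27, adjusted p = 4.29e-07) were higher. So were Syngr1 (log2 4.54 ± 0.30, adjusted p = 6.35e-16), Cd63 (log2 2.49 ± 0.33, adjusted p = 1.04e-07) and Spp1 (log2 1.36 ± 0.31, adjusted p = 9.24e-04). Lgals3 (log2 1.09 ± 0.29, adjusted p = 0.00514), Ctsd (log2 0.91 ± 0.30, adjusted p = 0.0257) and Capg (log2 0.74 ± 0.27, adjusted p = 0.0463) were higher too, and Plin2 (log2 0.38 ± 0.30, adjusted p = 0.464) was not past the threshold. Of 8932 genes, 878 were higher and 777 lower, 649 and 561 by at least 2-fold, and 95.8% of them had the same direction in both libraries. Lower genes were slightly more by DESeq2, at 634 against 590, and with size factors, at 884 against 882. From library 2 alone came a log2 of 3.65 for Syngr1 and 1.89 for Cd63. Ctsd and Capg lost their calls with thinned cells. Capg lost the call without a low-count filter.

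Against the alveolar-like cluster, 8 lists were higher and cholesterol synthesis was lower. With an estimated correlation, camera called 0 of them, 0 at an unadjusted p under 0.05. Cholesterol synthesis genes were lower (median log2 -1.30, adjusted p = 2.07e-06, 0 higher and 12 lower of 16, 0 and 13 adjusted over the list alone). Idi1, an enzyme of sterol synthesis (log2 -1.92 ± 0.41, adjusted p = 4.75e-04) was lower. Lysosome genes were higher (median log2 0.72, adjusted p = 4.51e-09, 12 higher and 0 lower of 23, 13 and 0 adjusted over the list alone). Ctsl (log2 3.28 ± 0.34, adjusted p = 3.46e-10) and Ctsb (log2 2.62 ± 0.28, adjusted p = 6.10e-10) were higher. Glycolysis genes were higher (median log2 0.64, adjusted p = 0.00412, 6 higher and 0 lower of 14, 7 and 0 adjusted over the list alone). Hk3 (log2 1.97 ± 0.27, adjusted p = 2.01e-07) and Slc2a1, a glucose transporter (log2 1.27 ± 0.31, adjusted p = 0.00186) were higher. Matrix genes and proteases were higher (median log2 0.88, adjusted p = 0.00412, 8 higher and 3 lower of 15, 9 and 3 adjusted over the list alone). Mmp12 (log2 3.52 ± 0.32, adjusted p = 1.01e-11) and Adam8, a sheddase (log2 3.12 ± 0.32, adjusted p = 2.28e-10) were higher. Growth and angiogenic factors were higher (median log2 0.67, adjusted p = 0.00332, 6 higher and 2 lower of 15, 8 and 2 adjusted over the list alone). Pdgfa (log2 3.84 ± 0.29, adjusted p = 4.31e-14) and Csf1, the macrophage growth factor (log2 3.35 ± 0.49, adjusted p = 7.12e-07) were higher. Phagocytosis genes were higher (median log2 0.90, adjusted p = 0.0399, 9 higher and 3 lower of 17, 9 and 3 adjusted over the list alone). Mfge8 (log2 4.52 ± 0.32, adjusted p = 6.95e-15) and Cd93 (log2 2.13 ± 0.23, adjusted p = 9.74e-10) were higher. Iron and oxidative stress genes were higher (median log2 0.62, adjusted p = 0.0141, 3 higher and 0 lower of 14, 4 and 0 adjusted over the list alone). Slc11a1 (log2 2.97 ± 0.29, adjusted p = 3.67e-11) and Slc7a11, a cystine transporter (log2 1.28 ± 0.30, adjusted p = 0.00107) were higher. Hypoxia response genes were higher (median log2 0.62, adjusted p = 0.0367, 2 higher and 0 lower of 10, 2 and 0 adjusted over the list alone). Ndrg1, a hypoxia-induced gene (log2 2.15 ± 0.36, adjusted p = 1.04e-05) and P4ha1, a collagen-modifying enzyme (log2 0.89 ± 0.29, adjusted p = 0.0244) were higher. MHC class I presentation genes were higher (median log2 0.71, adjusted p = 0.0111, 3 higher and 0 lower of 9, 5 and 0 adjusted over the list alone). H2-D1 (log2 1.46 ± 0.27, adjusted p = 6.64e-05) and H2-K1 (log2 1.15 ± 0.29, adjusted p = 0.00293) were higher. Csf1 rested on 16 and 0 UMIs in the alveolar-like cluster. Library 1 alone gave a log2 of 2.73 for Mmp12, 2.75 for Csf1 and 3.94 for Mfge8. In library 2 alone, the log2 was -0.37 for Idi1, 0.73 for Hk3, 4.67 for Mmp12, 3.24 for Pdgfa, 5.31 for Csf1, 2.27 for Slc11a1, 1.51 for P4ha1, -0.70 for the cholesterol synthesis list and 0.00 for the phagocytosis list. Idi1, Slc2a1 and P4ha1 lost their calls by DESeq2. Slc2a1, P4ha1, the growth factor list and the hypoxia response list lost their calls with thinned cells. The phagocytosis list and the hypoxia response list lost their calls with size factors. The phagocytosis list lost the call without a low-count filter. The phagocytosis list, the hypoxia response list and the MHC class I list lost their calls without the block. The phagocytosis list, the iron list and the hypoxia response list lost their calls under count splitting.

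The other 8 lists did not pass against the alveolar-like cluster. Genes of lipid uptake, storage and efflux did not pass (median log2 0.07, adjusted p = 0.2197, 3 higher and 6 lower of 19, 5 and 6 adjusted over the list alone). Olr1, a receptor for oxidized lipoprotein (log2 -3.30 ± 0.30, adjusted p = 9.62e-12) and Abcg1, a cholesterol exporter (log2 -2.48 ± 0.29, adjusted p = 3.65e-09) were lower. Fatty acid oxidation genes did not pass (median log2 -0.08, adjusted p = 0.159, 0 higher and 3 lower of 15, 0 and 4 adjusted over the list alone). Cpt1a, the gate to fatty acid oxidation (log2 -1.67 ± 0.28, adjusted p = 1.08e-05) and Etfb, an electron carrier (log2 -0.95 ± 0.28, adjusted p = 0.0109) were lower. Oxidative phosphorylation genes did not pass (median log2 -0.21, adjusted p = 0.159, 0 higher and 1 lower of 19, 0 and 0 adjusted over the list alone). Ndufa4, a respiratory chain subunit (log2 -0.80 ± 0.26, adjusted p = 0.0255) was lower. Inflammatory cytokines did not pass (median log2 -0.59, adjusted p = 0.05301, 1 higher and 6 lower of 16, 2 and 6 adjusted over the list alone). Il1a, an inflammatory cytokine (log2 -1.99 ± 0.35, adjusted p = 2.06e-05) and Nlrp3, an inflammasome sensor (log2 -1.55 ± 0.29, adjusted p = 4.58e-05) were lower. Chemokines did not pass (median log2 0.14, adjusted p = 0.0591, 4 higher and 1 lower of 14, 4 and 1 adjusted over the list alone). Cxcl16 (log2 2.32 ± 0.29, adjusted p = 1.61e-08) and Ccl2, a monocyte attractant (log2 1.95 ± 0.31, adjusted p = 4.01e-06) were higher. Immune regulation genes did not pass (median log2 0.31, adjusted p = 0.581, 3 higher and 2 lower of 14, 4 and 3 adjusted over the list alone). Arg1 (log2 2.35 ± 0.53, adjusted p = 8.95e-04) and Lgals9, a galectin (log2 1.22 ± 0.25, adjusted p = 2.79e-04) were higher. Complement genes did not pass (median log2 0.32, adjusted p = 0.673, 1 higher and 1 lower of 7, 2 and 2 adjusted over the list alone). C3ar1 (log2 2.96 ± 0.33, adjusted p = 2.17e-09) was higher. C5ar1 (log2 -1.18 ± 0.28, adjusted p = 0.00162) was lower. Dissociation and early response genes did not pass (median log2 -0.17, adjusted p = 0.872, 2 higher and 1 lower of 17, 3 and 2 adjusted over the list alone). Ier3, an early response gene (log2 1.35 ± 0.33, adjusted p = 0.00232) was higher. Fosb, an early response factor (log2 -1.46 ± 0.29, adjusted p = 1.39e-04) was lower. The lipid list had a mean of -0.23 and a test toward lower, and the dissociation list a mean of 0.04 and a test toward higher, each against the sign of its median. Inflammatory cytokines passed as lower and chemokines as higher in 8 alternatives each, and oxidative phosphorylation as lower in 3. The random lists were among these alternatives for inflammatory cytokines and oxidative phosphorylation, at percentiles 0 and 0.98. From library 2 alone came a log2 of 2.06 for C3ar1, -0.34 for the lipid list and -0.03 for the immune regulation list. Ndufa4 lost the call under count splitting. Arg1 and Ier3 lost their calls by DESeq2.

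**Figure D3:**
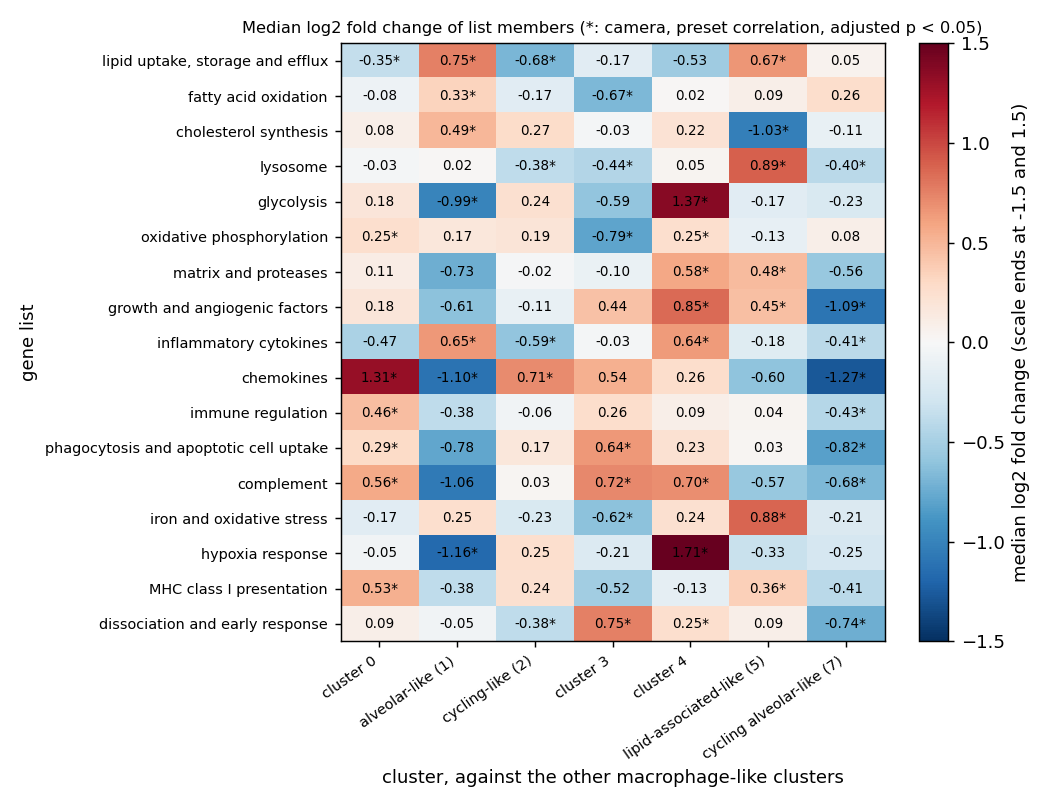
Median log2 fold change of the tested members of 17 gene lists in each macrophage-like cluster against the others, with an asterisk where camera with a preset correlation passed an adjusted p of 0.05. Lysosome stood at 0.89 in the lipid-associated-like cluster, glycolysis at 1.37 in cluster 4 and chemokines at 1.31 in cluster 0.

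To describe macrophage diversity, each other cluster was set against the remaining macrophage-like clusters. Further alternatives, below, are those besides the missing block and the estimated correlation. Cluster 0 held more of the chemokines, with Cxcl9 at 325 ± 14.5 CPM (SD, n = 2) against 82.9 ± 22.8. All 7 list calls here ended with an estimated correlation. Chemokines were higher (median log2 1.31, adjusted p = 8.56e-10, 9 higher and 1 lower of 14, 10 and 1 adjusted over the list alone). Cxcl9, a T cell attractant (log2 2.21 ± 0.18, adjusted p = 6.41e-13) and Cxcl13 (log2 2.05 ± 0.24, adjusted p = 1.46e-08) were higher. MHC class I presentation genes were higher (median log2 0.53, adjusted p = 5.82e-04, 4 higher and 0 lower of 9, 7 and 0 adjusted over the list alone). Tap1, a peptide transporter (log2 0.95 ± 0.16, adjusted p = 1.26e-05) and Psmb9, an immunoproteasome subunit (log2 0.76 ± 0.18, adjusted p = 0.00235) were higher. Complement genes were higher (median log2 0.56, adjusted p = 0.00223, 3 higher and 0 lower of 7, 6 and 0 adjusted over the list alone). Cfb, a complement protease (log2 0.94 ± 0.18, adjusted p = 9.66e-05) and C3ar1 (log2 0.94 ± 0.21, adjusted p = 7.45e-04) were higher. Genes of lipid uptake, storage and efflux were lower (median log2 -0.35, adjusted p = 0.00408, 2 higher and 6 lower of 19, 3 and 8 adjusted over the list alone). Olr1 (log2 -2.36 ± 0.26, adjusted p = 1.68e-09) and Fabp4 (log2 -1.76 ± 0.29, adjusted p = 1.25e-05) were lower. Phagocytosis genes were higher (median log2 0.29, adjusted p = 0.0203, 8 higher and 0 lower of 17, 8 and 1 adjusted over the list alone). Timd4, a receptor for apoptotic cells (log2 2.18 ± 0.52, adjusted p = 0.00211) and Fcgr1, an Fc receptor (log2 1.09 ± 0.17, adjusted p = 2.53e-06) were higher. Immune regulation genes were higher (median log2 0.46, adjusted p = 0.0279, 6 higher and 1 lower of 14, 7 and 1 adjusted over the list alone). Pdcd1lg2, a ligand of the PD-1 receptor (log2 1.26 ± 0.22, adjusted p = 2.00e-05) and Retnla, a marker of alternative activation (log2 1.18 ± 0.30, adjusted p = 0.00373) were higher. The oxidative phosphorylation list as a whole passed as higher (median log2 0.25, adjusted p = 0.0437, 0 higher and 0 lower of 19, 0 and 0 adjusted over the list alone). No single member passed. Cox4i1 (log2 0.08 ± 0.21, adjusted p = 0.837), the member with the highest mean count, was not past the threshold. Of all 8932 genes, 729 were higher and 712 lower, 94.4% of them with the same direction in both libraries. With size factors in place of TMM, 644 were higher and 1029 lower. Lower genes also outnumbered higher ones by DESeq2, under count splitting and with a single summed arm. Library 1 alone gave a log2 of 1.16 for Timd4. In library 2 alone, the log2 was 1.99 for Cfb, -0.53 for Fabp4 and 2.26 for Pdcd1lg2. The calls of Psmb9, C3ar1, Timd4, Pdcd1lg2, Retnla, the MHC class I list, the phagocytosis list, the immune regulation list and the oxidative phosphorylation list ended in at least 1 further alternative.

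The alveolar-like cluster held more of the lipid genes and less of glycolysis, with Abcg1 at 438 ± 87.3 CPM (SD, n = 2) against 58.8 ± 27.5. All 7 list calls here ended with an estimated correlation. Genes of lipid uptake, storage and efflux were higher (median log2 0.75, adjusted p = 6.35e-06, 10 higher and 1 lower of 19, 10 and 1 adjusted over the list alone). Olr1 (log2 3.36 ± 0.17, adjusted p = 5.88e-21) and Abcg1 (log2 3.21 ± 0.17, adjusted p = 4.49e-20) were higher. Glycolysis genes were lower (median log2 -0.99, adjusted p = 8.37e-05, 0 higher and 11 lower of 14, 0 and 12 adjusted over the list alone). The glycolytic enzymes Eno1 (log2 -1.59 ± 0.32, adjusted p = 1.37e-04) and Tpi1 (log2 -1.43 ± 0.29, adjusted p = 1.71e-04) were lower. Chemokines were lower (median log2 -1.10, adjusted p = 0.00107, 1 higher and 9 lower of 14, 1 and 9 adjusted over the list alone). Cxcl13 (log2 -1.92 ± 0.42, adjusted p = 3.81e-04) and Ccl2 (log2 -1.91 ± 0.27, adjusted p = 1.62e-07) were lower. Hypoxia response genes were lower (median log2 -1.16, adjusted p = 0.00236, 0 higher and 7 lower of 10, 0 and 8 adjusted over the list alone). Ndrg1 (log2 -2.05 ± 0.30, adjusted p = 4.06e-07) and Ankrd37 (log2 -1.76 ± 0.31, adjusted p = 1.82e-05) were lower. Inflammatory cytokines were higher (median log2 0.65, adjusted p = 0.0116, 8 higher and 1 lower of 16, 10 and 1 adjusted over the list alone). Il1a (log2 2.05 ± 0.22, adjusted p = 1.98e-10) and Tnf (log2 1.93 ± 0.26, adjusted p = 7.50e-08) were higher. Cholesterol synthesis genes were higher (median log2 0.49, adjusted p = 0.02505, 4 higher and 0 lower of 16, 9 and 0 adjusted over the list alone). Insig1, a brake on sterol synthesis (log2 0.95 ± 0.20, adjusted p = 2.38e-04) and Hmgcs1, an enzyme of sterol synthesis (log2 0.89 ± 0.20, adjusted p = 4.01e-04) were higher. Fatty acid oxidation genes were higher (median log2 0.33, adjusted p = 0.0358, 6 higher and 0 lower of 15, 6 and 0 adjusted over the list alone). Cpt1a (log2 1.60 ± 0.17, adjusted p = 3.64e-10) and Hadhb (log2 0.90 ± 0.19, adjusted p = 2.26e-04) were higher. Of all 8932 genes, 1234 were higher and 1234 lower, 94.6% of them with the same direction in both libraries. From library 2 alone came a log2 of -0.19 for Cxcl13, 2.91 for Il1a, 2.60 for Tnf, 2.20 for Insig1 and 1.57 for Hadhb. At least 1 further alternative ended the calls of Cxcl13, the inflammatory list, the cholesterol synthesis list and the fatty acid oxidation list.

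Cycling-like cluster 2 held less of the lipid, lysosome and inflammatory genes and more of the chemokines, with Ccl12 at 651 ± 49.2 CPM (SD, n = 2) against 369 ± 17.6. All 5 list calls here ended with an estimated correlation. Genes of lipid uptake, storage and efflux were lower (median log2 -0.68, adjusted p = 6.35e-06, 1 higher and 10 lower of 19, 1 and 14 adjusted over the list alone). Fabp4 (log2 -2.29 ± 0.32, adjusted p = 3.10e-07) and Olr1 (log2 -1.49 ± 0.24, adjusted p = 6.43e-06) were lower. Lysosome genes were lower (median log2 -0.38, adjusted p = 0.00145, 0 higher and 3 lower of 23, 0 and 2 adjusted over the list alone). Atp6v1a, a proton pump subunit (log2 -0.74 ± 0.17, adjusted p = 0.001402) and Gla, a lysosomal glycosidase (log2 -0.58 ± 0.19, adjusted p = 0.0214) were lower. Inflammatory cytokines were lower (median log2 -0.59, adjusted p = 0.00746, 0 higher and 6 lower of 16, 0 and 8 adjusted over the list alone). Tnf (log2 -1.43 ± 0.33, adjusted p = 0.00101) and Il1a (log2 -1.25 ± 0.26, adjusted p = 3.29e-04) were lower. Chemokines were higher (median log2 0.71, adjusted p = 0.0131, 9 higher and 0 lower of 14, 10 and 1 adjusted over the list alone). Ccl17, a T cell attractant (log2 1.75 ± 0.39, adjusted p = 7.00e-04) and Ccl12, a monocyte attractant (log2 1.33 ± 0.20, adjusted p = 1.03e-06) were higher. Dissociation and early response genes were lower (median log2 -0.38, adjusted p = 0.0323, 1 higher and 5 lower of 17, 1 and 7 adjusted over the list alone). Egr1, an early response factor (log2 -0.99 ± 0.25, adjusted p = 0.00237) and Klf4, a transcription factor (log2 -0.91 ± 0.22, adjusted p = 0.00182) were lower. Of all 8932 genes, 1061 were higher and 745 lower, 94.8% of them with the same direction in both libraries. With count splitting, 996 were higher and 1146 lower. The chemokine list turned to a median of -0.17 with the other clusters summed as a single arm. Library 1 alone gave a log2 of 0.94 for Ccl17. In library 2 alone, the log2 was -0.97 for Fabp4 and -0.59 for Tnf. At least 1 further alternative ended the calls of Olr1, Gla, Tnf, Il1a, Ccl17, Ccl12, Egr1, the chemokine list and the dissociation list.

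Cluster 3 had medians of 1014 UMIs and a mitochondrial share of 14.7% in library 1, and of 1096 UMIs and 19.8% in library 2. Stress genes were higher, with Hspa1b at 289 ± 51.4 CPM (SD, n = 2) against 64.6 ± 9.24, although its reads can be split with its copy Hspa1a. All 7 list calls here ended with an estimated correlation. Oxidative phosphorylation genes were lower (median log2 -0.79, adjusted p = 6.43e-11, 0 higher and 15 lower of 19, 0 and 17 adjusted over the list alone). Sdhd, a succinate dehydrogenase subunit (log2 -2.47 ± 0.34, adjusted p = 3.77e-07) and Cox5a, a subunit of cytochrome oxidase (log2 -2.13 ± 0.25, adjusted p = 1.76e-08) were lower. Yet respiratory chain genes such as mt-Nd1 led this cluster. Dissociation and early response genes were higher (median log2 0.75, adjusted p = 1.16e-07, 13 higher and 0 lower of 17, 13 and 0 adjusted over the list alone). Hspa1b (log2 2.56 ± 0.18, adjusted p = 7.85e-15) and Hspa1a, its near-identical copy (log2 1.97 ± 0.20, adjusted p = 5.04e-10) were higher. Fatty acid oxidation genes were lower (median log2 -0.67, adjusted p = 0.00223, 0 higher and 5 lower of 15, 0 and 7 adjusted over the list alone). Etfa, an electron carrier (log2 -1.39 ± 0.27, adjusted p = 1.52e-04) and Echs1 (log2 -1.10 ± 0.24, adjusted p = 8.08e-04) were lower. Lysosome genes were lower (median log2 -0.44, adjusted p = 0.0107, 2 higher and 9 lower of 23, 2 and 9 adjusted over the list alone). Atp6v0c, a proton pump subunit (log2 1.23 ± 0.37, adjusted p = 0.0105) was higher. Ctsl (log2 -0.98 ± 0.27, adjusted p = 0.005699) was lower. Iron and oxidative stress genes were lower (median log2 -0.62, adjusted p = 0.0337, 2 higher and 6 lower of 14, 3 and 7 adjusted over the list alone). Prdx1, a peroxidase (log2 -1.35 ± 0.24, adjusted p = 6.21e-05) and Fth1 (log2 -1.17 ± 0.23, adjusted p = 2.22e-04) were lower. Phagocytosis genes were higher (median log2 0.64, adjusted p = 0.0437, 8 higher and 1 lower of 17, 9 and 1 adjusted over the list alone). Stab1, a scavenger receptor (log2 2.28 ± 0.22, adjusted p = 4.42e-11) and Itgam, an integrin (log2 1.42 ± 0.27, adjusted p = 9.60e-05) were higher. Complement genes were higher (median log2 0.72, adjusted p = 0.0458, 4 higher and 0 lower of 7, 4 and 0 adjusted over the list alone). C4b, complement component C4 (log2 2.51 ± 0.23, adjusted p = 1.23e-11) was higher. Of all 8932 genes, 1506 were higher and 1188 lower, 93.8% of them with the same direction in both libraries. With size factors, 2329 were higher and 784 lower. The balance turned to 1321 higher and 1715 lower with at least 30 cells, 1041 and 1306 with own clusters, 1318 and 1478 without top doublet scores, and 1299 and 1355 without cycling clusters. From library 2 alone came a log2 of -1.73 for Sdhd, -1.75 for Echs1, 0.75 for Itgam, 1.77 for C4b and 0.03 for the phagocytosis list. The calls of Echs1, Atp6v0c, Ctsl, the fatty acid oxidation list, the lysosome list, the iron list, the phagocytosis list and the complement list ended in at least 1 further alternative.

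Cluster 4 held more of the glycolysis and hypoxia genes, with Eno1 at 1736 ± 573 CPM (SD, n = 2) against 615 ± 356. All 8 list calls here ended with an estimated correlation. Glycolysis genes were higher (median log2 1.37, adjusted p = 1.01e-18, 13 higher and 0 lower of 14, 13 and 0 adjusted over the list alone). Slc2a1 (log2 1.87 ± 0.17, adjusted p = 2.85e-11) and Eno1 (log2 1.74 ± 0.25, adjusted p = 9.10e-07) were higher. Hypoxia response genes were higher (median log2 1.71, adjusted p = 4.89e-17, 9 higher and 0 lower of 10, 9 and 0 adjusted over the list alone). Egln3, an oxygen sensor (log2 2.81 ± 0.28, adjusted p = 2.93e-10) and Ankrd37 (log2 2.20 ± 0.21, adjusted p = 9.60e-11) were higher. Inflammatory cytokines were higher (median log2 0.64, adjusted p = 1.63e-06, 7 higher and 0 lower of 16, 9 and 0 adjusted over the list alone). Il6 (log2 4.12 ± 0.26, adjusted p = 7.39e-16) and Cxcl3 (log2 2.55 ± 0.33, adjusted p = 1.02e-07) were higher. Matrix genes and proteases were higher (median log2 0.58, adjusted p = 0.001596, 7 higher and 2 lower of 15, 8 and 2 adjusted over the list alone). Adam8 (log2 2.05 ± 0.19, adjusted p = 4.01e-11) and Fn1, fibronectin (log2 2.05 ± 0.26, adjusted p = 1.02e-07) were higher. Complement genes were higher (median log2 0.70, adjusted p = 0.00746, 4 higher and 0 lower of 7, 4 and 2 adjusted over the list alone). C4b (log2 1.78 ± 0.19, adjusted p = 7.41e-10) was higher. Oxidative phosphorylation genes were higher (median log2 0.25, adjusted p = 0.0222, 1 higher and 0 lower of 19, 1 and 0 adjusted over the list alone). Sdhd (log2 0.61 ± 0.19, adjusted p = 0.0328) was higher. Dissociation and early response genes were higher (median log2 0.25, adjusted p = 0.02505, 3 higher and 0 lower of 17, 3 and 0 adjusted over the list alone). Ier3 (log2 1.41 ± 0.22, adjusted p = 5.70e-06) and Klf2, a transcription factor (log2 1.11 ± 0.20, adjusted p = 7.36e-05) were higher. Growth and angiogenic factors were higher (median log2 0.85, adjusted p = 0.0305, 7 higher and 5 lower of 15, 8 and 5 adjusted over the list alone). Adm, a vasodilator peptide (log2 4.93 ± 0.47, adjusted p = 6.65e-11) and Hbegf, an epidermal growth factor relative (log2 2.78 ± 0.26, adjusted p = 2.85e-11) were higher. Of all 8932 genes, 565 were higher and 229 lower, 97.5% of them with the same direction in both libraries. With size factors, 461 were higher and 425 lower. The chemokine list, not past the threshold, turned to a median of -0.53 with the other clusters summed as a single arm. Library 1 alone gave a log2 of 3.61 for Egln3, 2.94 for Ankrd37, 2.77 for Fn1 and 3.75 for Adm. In library 2 alone, the log2 was 1.86 for Egln3, 1.40 for Ankrd37, 3.49 for Il6, 3.73 for Cxcl3, 1.34 for Fn1, 4.14 for Adm, 2.05 for Hbegf and 0.16 for the growth factor list. The calls of Cxcl3, Sdhd, Klf2, the matrix list, the complement list, the oxidative phosphorylation list, the dissociation list and the growth factor list ended in at least 1 further alternative.

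Cycling alveolar-like cluster 7 held less of the chemokines, with Ccl2 at 54.7 ± 38.9 CPM (SD, n = 2) against 233 ± 79.2. All 8 list calls here ended with an estimated correlation. Igf1, Hbegf, Ptgs2 and Mfge8 had at most 3 UMIs there over both libraries and are given no fold. Pdcd1lg2 had 6 UMIs there in library 1 and 0 in library 2, and C4b 4 and 1, so their folds are imprecise. Dissociation and early response genes were lower (median log2 -0.74, adjusted p = 2.25e-06, 0 higher and 9 lower of 17, 0 and 11 adjusted over the list alone). Hspa1b (log2 -2.81 ± 0.36, adjusted p = 3.29e-08) and Hspa1a (log2 -1.68 ± 0.33, adjusted p = 1.40e-04) were lower. Chemokines were lower (median log2 -1.27, adjusted p = 1.86e-04, 0 higher and 6 lower of 14, 0 and 8 adjusted over the list alone). Ccl2 (log2 -2.21 ± 0.34, adjusted p = 2.33e-06) and Ccl7, a monocyte attractant (log2 -2.20 ± 0.35, adjusted p = 3.28e-06) were lower. Phagocytosis genes were lower (median log2 -0.82, adjusted p = 7.40e-04, 1 higher and 7 lower of 17, 1 and 12 adjusted over the list alone). Stab1 (log2 -2.03 ± 0.41, adjusted p = 2.11e-04) was lower. Lysosome genes were lower (median log2 -0.40, adjusted p = 0.00499, 0 higher and 5 lower of 23, 0 and 5 adjusted over the list alone). Ctsb (log2 -1.25 ± 0.23, adjusted p = 6.08e-05) and Psap, a lysosomal lipid carrier (log2 -0.83 ± 0.24, adjusted p = 0.0118) were lower. Immune regulation genes were lower (median log2 -0.43, adjusted p = 0.0222, 0 higher and 4 lower of 14, 0 and 6 adjusted over the list alone). Pdcd1lg2 (log2 -1.71 ± 0.59, adjusted p = 0.0387) and Il4ra, the interleukin 4 receptor (log2 -1.16 ± 0.27, adjusted p = 0.001501) were lower. Complement genes were lower (median log2 -0.68, adjusted p = 0.02505, 0 higher and 3 lower of 7, 0 and 3 adjusted over the list alone). C4b (log2 -2.85 ± 0.52, adjusted p = 4.74e-05) and C3ar1 (log2 -1.62 ± 0.37, adjusted p = 9.91e-04) were lower. Inflammatory cytokines were lower (median log2 -0.41, adjusted p = 0.0276, 1 higher and 5 lower of 16, 1 and 5 adjusted over the list alone). Ccl4, a chemokine (log2 -1.49 ± 0.38, adjusted p = 0.00328) was lower. Growth and angiogenic factors were lower (median log2 -1.09, adjusted p = 0.0437, 2 higher and 6 lower of 15, 2 and 7 adjusted over the list alone). Of all 8932 genes, 780 were higher and 607 lower, 81.8% of them with the same direction in both libraries. With a single summed arm, 319 were higher and 352 lower. In library 1, 217 of 218 cells were closest to the alveolar-like profile. In library 2, 1 of 10 was and 9 of 10 were closest to cluster 4, so the name holds for library 1. From library 1 alone came a log2 of -2.37 for Hspa1a, -2.78 for Stab1, -2.33 for C3ar1, -1.03 for the immune regulation list, -1.55 for the complement list and 0.07 for the inflammatory list. Library 2 alone gave a log2 of -1.39 for Hspa1b, -0.44 for Hspa1a, -1.58 for Ccl2, -1.20 for Ccl7, -0.57 for Stab1, -4.35 for Pdcd1lg2, -1.82 for C4b, -0.13 for C3ar1, -2.50 for Ccl4, -2.16 for the inflammatory list and -1.77 for the growth factor list. The calls of Psap, Pdcd1lg2, C3ar1, the lysosome list, the complement list, the inflammatory list and the growth factor list ended in at least 1 further alternative.

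Whether the lipid-associated-like cells divided was read from cycling markers such as Mki67 and Top2a. Cells were thinned to 1000 UMIs, which left out shallower cells, among them 445 of 913 and 92 of 212 cells of cluster 3. Of the rest, 1 of 600 lipid-associated-like cells of library 1 had at least 3 UMIs of them (0.167%, 0.00422 to 0.925), and 0 of 73 in library 2, which allows a share of up to 4.11%. Cluster 0 had 3.02% (2.44 to 3.69) and 1.65% (0.759 to 3.12), alveolar-like cells 0.764% (0.485 to 1.14) and 1.46% (0.303 to 4.22). Cluster 3 had 2.99% (1.64 to 4.97) and 2.5% (0.519 to 7.13), and cluster 4 had 3.07% (1.86 to 4.75) and 2.27% (0.839 to 4.88). Cycling-like cluster 2 had 63.1% (60.8 to 65.4) and 46.96% (39.5 to 54.5), and cluster 7 had 87.2% (81.97 to 91.3) and 70% (34.8 to 93.3). T cell-like cells had 9.30% (4.8995 to 15.7) and 7.41% (0.910 to 24.3), and dendritic-like cells 0.935% (0.0237 to 5.097) and 7.69% (0.195 to 36.03). Neutrophil-like cells had 4.55% (2.51 to 7.51) in library 1 and 0 of 17 in library 2 (up to 17.6%). Alveolar-like cells of library 1 lay lower, so 4.55% sets no background. The clusters were made partly on cycling genes, so the low share does not show that lipid-associated-like cells do not divide.

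Markers of other cell types checked the sort and free RNA, as the share of cells with at least 2 UMIs over a list. The neutrophil list was in 64.4% and 79.3% of the cells of libraries 1 and 2. Macrophage-like cells, which should lack it, had 62.9% and 79.7% (median 3771 and 6366 UMIs). There the neutrophil genes, such as S100a8, made up 0.0785% and 0.114% of UMIs, against 13.8% and 18.3% in neutrophil-like cells (median 1928 and 1553.5 UMIs). The T cell list, such as Cd3d, was in 9.65% and 5.62% of cells, 8.97% and 4.21% of macrophage-like cells, and 88.4% and 83.3% of T cell-like cells (median 3518 and 2195 UMIs). The epithelial or tumour cell list, such as Krt8, was in 2.58% and 3.06% of cells, 2.38% and 2.94% of macrophage-like cells, and 46.2% and 50% of cluster 10 (median 11021 and 572.5 UMIs). The conventional dendritic cell list was in 1.89% and 3.25% of cells, 1.18% and 3.14% of macrophage-like cells, and 57.4% of dendritic-like cells of library 1 (median 4924 UMIs). The shares of further lists over all cells were close to those of macrophage-like cells, which make up most cells, and so say little of small clusters. These were B cell, 9.17% and 2.62% (9.40% and 2.60% of macrophage-like cells), NK cell, 1.72% and 1.53% (1.66% and 1.40%), and plasmacytoid dendritic cell, 3.28% and 4.79% (3.19% and 4.94%). The B cell list was in 11.6% and 6.67% of T cell-like cells, and in 24.1% and 5.52% of cycling-like cluster 2. The NK cell list was in 10.1% and 10% of T cell-like cells. The plasmacytoid dendritic cell list was in 33.3% of cluster 10 of library 1. The remaining lists were endothelium, 0.738% and 2.43% (0.742% and 2.54%), alveolar type 2 epithelium, 0.291% and 0.447% (0.293% and 0.467%), and erythroid, 0.0729% and 5.68% (0.0781% and 5.87%). The platelet list was in 0.0455% and 0.319%, fibroblast in 0.0546% and 0%, mast cell or basophil in 0.0273% and 0%, and eosinophil (1 gene) in 0.00911% and 0%. Each 0 of 1567 cells allows a share of up to 0.191%. The median ratio of 6 macrophage transcripts, Lyz2, Cd68, Tyrobp, Fcer1g, Csf1r and Ctss, to macrophage-like cells was 0.720 and 0.632 in neutrophil-like, 0.776 and 0.640 in T cell-like, and 0.555 and 0.867 in dendritic-like cells.

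Cluster profiles of the libraries were compared across genes, which are not independent replicates, so no p-value is given. For lipid-associated-like cells, Pearson's r was 0.772 and Spearman's rho 0.674 over 2068 genes with a mean of at least 50 CPM. The 10 genes of highest fold in library 1 alone, led by Gpnmb, Syngr1 and Fabp5, were positive in library 2, 9 over 2-fold. Their median log2 was 2.90 and 2.59 in libraries 1 and 2. Pearson's r was 0.849 for alveolar-like, 0.835 for cluster 0, 0.833 for cluster 2, 0.768 for cluster 3 and 0.722 for cluster 4, with rho of 0.748, 0.749, 0.799, 0.767 and 0.641. It was 0.804 for neutrophil-like, 0.691 for T cell-like and 0.537 for dendritic-like cells, with rho of 0.671, 0.475 and 0.3796. Cluster 7 gave 0.487 (rho 0.341) and -0.0162 with thinned cells, where library 2 has 10 cells.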

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

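The tests by Scrublet score, by UMIs dealt at random and by a mixture of marker levels, and the levels of Malat1, were chosen only after the result was seen. The doublet ratio and the nearest-profile test were set out before, but they met their marks and are read more strictly here because of values seen afterwards. No biological explanation was tested, since the design has 1 group.

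Cluster 10 lay outside every comparison and held 0.355% of the cells of library 1 (39 cells, 95% interval 0.253 to 0.485) and 0.383% of library 2 (6 cells, 0.141 to 0.832), above the 0.0273% and 0.191% that a count of 0 allows, as any cluster with more than 3 cells lies; the interval of library 2 includes its limit. Alveolar type 2 epithelium was argued against as the whole cluster: 1 of 39 cells had 5 or more UMIs of that list (2.56%, 0.0649 to 13.5), and a single cell held 99.8% of its Sftpc UMIs in library 1. Free RNA was argued against as the source of Krt8 and Krt18: their share of UMIs was 257 and 232 times that of macrophage-like cells in libraries 1 and 2, past the 10 set before as going against it, and, as both genes lead the cluster, the UMIs were also dealt to cells at random in 1000 draws, and the cluster held 6.01 and 3.40 times the most that as many cells then held (17 of 39 cells with Krt8 in library 1, but 87.2% of it in 1 of 6 cells in library 2). Doublets of a macrophage with another cell stay open. The 6 macrophage transcripts stood at 0.356 of their macrophage level (0.271 to 0.466), past the 0.25 set as the doublet mark. T cell-like cells (0.776 in library 1) may also be doublets and are no control. Of the 39 cells, 0 (0%, which allows a share of up to 7.69%) were among the top 5% of Scrublet scores, a method that found no separate doublets in library 1.

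Cluster 3 was led by mitochondrial transcripts, and damaged cells of the other clusters stay open. Malat1, a nuclear transcript, stood at 51725 and 55291 CPM of unscaled totals there, against 9975 to 18157 in the other macrophage-like clusters of library 1 and 18475 to 28647 in library 2. In its 27 low-mitochondrial cells of library 1, 10 genes picked in its other cells of that library, such as Maf, Cxcl13 and Stab1, kept a median log2 of 1.86, with 9 of 10 positive. In the 5 such cells of library 2, 10 genes picked there, with Hes1 and Cx3cr1 in place of Cxcl13 and Stab1, had a median of -0.83, with 4 of 10 positive. The gene sets differ between the libraries and the cells are few.

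Few lipid-associated-like cells carried cycling markers, and clustering on cell cycle genes may have moved such cells into cycling-like cluster 2. With those genes left out, 8.62% of 1706 cluster 2 cells of library 1 were closest to the lipid-associated-like profile (7.33 to 10.05), which met the mark of 8.26%, their share of non-cycling cells. Held-out cluster 0 cells were placed there more often (13.1%), so this decides nothing; in library 2 the shares were 2.76% of cluster 2, 1.07% of cluster 0 and 6.67% of non-cycling cells. The levels of 10 genes such as Gpnmb and Fabp5 in cluster 2 allowed a median of 0.592% such cells in library 1 (-11.2 to 7.14) and 0.0265% in library 2 (-14.5 to 2.81), with 10 of 10 genes below the non-cycling share in each. That reading assumes that dividing cells keep their marker levels, so the question stays open.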

How the results depend on the processing

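Genes listed for both libraries and leaving out cluster 3, cycling clusters or top Scrublet scores were chosen only after results were seen. Each other alternative was planned. Values after a change are given beside those reported; where no reason is given, the cause was not tested.

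Named genes kept their direction and side of 0.05 in 2048 of 2210 comparisons with alternatives other than leaving out a library. A call was lost in 160, gained in 2 and reversed in 0. Without the block, 95 of 169 lost it, in part because the spread between libraries then counts as error. Functional lists kept theirs in 1528 of 1785, were weaker in 158, stronger in 96 and reversed in 3. Leaving out library 1 moved 69 of 169 gene folds and 64 of 136 list medians by more than the spread between libraries. Leaving out library 2 moved 15 and 33. Of medians past the threshold, 1 reversed. Others near 0 that changed sign count as moved or kept. Counts of genes stayed within 1.5 times in 155 of 206, and counts of lists in 49 of 74. Of cluster shares with a match, 43 of 60 stayed within their interval, and of marker shares 26 of 122. Of 20 correlations between libraries, 19 moved and 1 reversed.

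No library block moved the number of genes higher and lower in the lipid-associated-like cluster from 796 and 535 to 181 and 38, and against the alveolar-like cluster to 136 and 134. It gave 53 and 9 in cluster 0, 348 and 150 in the alveolar-like cluster, 249 and 10 in cluster 2, 261 and 81 in cluster 3, and 318 and 99 in cluster 7. Cluster 4 had 42 higher and 0 lower by edgeR (206 lower at an unadjusted p under 0.05), against 177 lower by DESeq2 with the block. Lists higher in the lipid-associated-like against the alveolar-like cluster fell from 8 to 5.

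Thinning every cell to 1000 UMIs, which removes counts, left 289 higher and 165 lower genes in the lipid-associated-like cluster, and 374 and 321 against the alveolar-like one. It left 327 and 229 in cluster 0, 599 and 521 in the alveolar-like cluster, 404 and 235 in cluster 2, 594 and 344 in cluster 3, 239 and 66 in cluster 4, and 338 and 237 in cluster 7. Lists lower against the alveolar-like cluster went from 1 to 2. Pearson's r between libraries was 0.503 for lipid-associated-like cells and turned to -0.0162 for cluster 7, from 0.772 and 0.487. With a mean of at least 10 CPM it was 0.640 for lipid-associated-like cells.

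Summing the other clusters as a single arm gave 459 genes higher in the lipid-associated-like cluster, 483 in cluster 0, 631 in cluster 2, 307 in cluster 4, 882 higher and 620 lower in cluster 3, and 319 and 352 in cluster 7. Lists lower in the lipid-associated-like cluster went to 3, and list and cluster pairs higher in the others from 22 to 12. The chemokine median reversed from 0.71 to -0.17 in cluster 2 and from 0.26 to -0.53 in cluster 4; clusters with more UMIs weigh more in such an arm, but the cause was not tested.

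The DESeq2 Wald test called 372 genes higher in cluster 0 (729 by edgeR), 679 higher in cluster 2 (1061), 682 lower in cluster 3 (1188), 295 higher in cluster 4 (565) and 399 lower in cluster 7 (607). RLE size factors gave 2329 higher and 784 lower in cluster 3 (1506 and 1188) and 425 lower in cluster 4 (229). They move the median log2 of all genes by 0.22 in cluster 3 and -0.10 in cluster 4. Without a low-count filter, pairs higher went to 12. At least 30 cells per library gave 1898 genes higher in the alveolar-like cluster (1234). Count splitting gave 1146 lower in cluster 2 (745), and the hypoxia median in cluster 0 reversed from -0.05 to 0.69. Without cycling clusters 2 and 7, 355 were lower in cluster 4.

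With an estimated inter-gene correlation, camera called 0 lists in each direction in the lipid-associated-like cluster, against the alveolar-like cluster and in the other clusters, from 6 and 1, 8 and 1, and 22 and 20. That ended the calls of 58 of 136 lists. At an unadjusted p under 0.05 it left 4 higher and 0 lower, 0 and 0, and 9 and 6. The test against random lists called 3 lower lists in each comparison of the lipid-associated-like cluster.

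Lists lower in the lipid-associated-like cluster went from 1 to 2 with Scrublet doublets left out, with count splitting and without cluster 3, and to 3 with at least 30 cells, own Leiden clusters, random lists and without cycling clusters. Against the alveolar-like cluster they went from 1 to 2 with Scrublet doublets left out, count splitting, the fit of 2 clusters alone and without cycling clusters, and to 3 with at least 30 cells, own Leiden clusters and random lists. Leaving out Scrublet doublets, at least 30 cells, own clusters and count splitting each also took cluster 7 out of the fit, so the moves cannot be put down to the named change alone.

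Library 1 clustered alone by the authors gave 30.7% of cells in cluster 0, 25.6% alveolar-like, 14.95% in cluster 2, 7.10% in cluster 3, 6.13% in cluster 4 and 2.88% in cluster 7. Library 2 alone gave 9.16% in cluster 2, 22.4% in cluster 4 and 3.33% lipid-associated-like. Own clustering gave 30.7% in cluster 0, 26.5% alveolar-like and 5.19% in cluster 4 of library 1, and 20.5% in cluster 4 and 0.128% in cluster 7 of library 2. The lipid-associated-like cluster overlapped the authors' with a Jaccard index of 0.889 by own clustering, 0.778 under count splitting, and 0.843 and 0.689 in libraries 1 and 2 alone. Cluster 3 had 0.637, 0.638, 0.338 and 0.443. Cluster 10 had 0.378 under count splitting and no match in the others. Clusters 7 and 9 had none in library 2 alone.

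Shares of marker-bearing cells follow the minimum by construction. Cycling lipid-associated-like cells were 1.17% and 6.85% with at least 2 UMIs, 0% in library 1 with at least 5, and 8.69% and 27.4% without thinning, where deeper cells gain markers. With at least 1 UMI, the neutrophil list was in 85.9% and 89.98% of all cells, the T cell list in 24.5% and 18.7%, and the epithelial or tumour cell list in 12.55% and 15.3%. With at least 5, these were 19.3% and 50.03%, 1.21% and 1.34%, and 0.237% and 0.191%.

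From each library alone, the inflammatory cytokine median of cluster 7 ranged from -2.16 to 0.068. A library alone gives folds and no test, and DESeq2 no list test. Cluster 7 had too few cells of library 2 with Scrublet doublets or top scores left out, with at least 30 cells, with own clusters and with count splitting, where cluster 4 was also absent. Library 2, with 1567 cells, limits each comparison.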

Other observations

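These values, in CPM of unscaled totals, were singled out only after they were seen. Arg1 stood at 61.0 CPM in cycling alveolar-like cluster 7 of library 1 and at 2765 CPM in library 2, against 2978 and 3397 CPM in cluster 4. Itgam stood at 15.95 and 257 CPM in cluster 7. Spp1 stood at 3433 and 2221 CPM in the lipid-associated-like cluster and at 3876 and 2852 CPM in cluster 4. In library 2, 10 cells made up cluster 7.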
